A study of Homo sapiens with 9 samples.

How the data were processed

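Gene expression was measured by RNA sequencing in 9 samples of PANC-1 cells, 3 each at day 0, day 2 and day 14 of nutrient and oxygen deprivation. RNA was extracted with a Qiagen kit and the libraries were built by a commercial company, per the labels' protocols. The authors deposited 1 table of TPM per gene symbol for the 9 samples, made with Salmon, a transcript quantifier, and naming the genome build hg19, per the submitters' processing notes. The Salmon version, the transcript annotation, the strand setting and any read filter were not given in the sources used here. TPM divides each gene's estimated reads by transcript length and scales each library to the same sum, so values are relative within a library and keep no depth. A rise of a few abundant entries lowers all others, and short entries with few reads can take a large share.

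Each column was assigned to a sample by the day and replicate number in its name, and groups were taken from the sample titles. The table had 27800 symbols and each column summed to 1000000. No nonzero value was shared by a pair of libraries, so no library was treated as a duplicate. Replicate numbers were shared between days. Symbols are reported as deposited, without coordinates, because no hg19 annotation was used here. GENCODE transcripts of another build (GRCh38) were used only for transcript lengths and for sequence matching, and 25430 symbols matched directly and 237 through an older symbol (92.3% of 27800).

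Values were analysed as log2(TPM + 1), and fold changes on this scale understate the change of low genes. Genes with at least 1 TPM in at least 3 of 9 libraries were tested, 14144 in all. Each comparison of days (day 2 against day 0, day 14 against day 0, day 14 against day 2) was tested with limma 3.58.1 in R 4.3.3, in 1 fit of all 9 libraries with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the tested genes within a comparison at 0.05. A moderated F test covered the 3 days together. Lists of genes were tested with camera from limma with a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 3 tested members, and again with an estimated correlation, under which no list call against day 0 held and 1 between day 14 and day 2 held. The rotation test fry was run beside it; it tests whether a list's genes move one way on balance and makes no comparison with other genes. There were 35 lists in all, and 8 genes were in more than 1 list. Where the median change of a list is given, it is also given relative to the median of all genes, because scaling moved that median by over 0.1. The set test compares a list with the other genes, so a list can pass as lower with little change of its own. Quantities are the mean ± SD of 3 libraries in TPM, and log2 changes carry their standard error where given.

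The rule for named genes took for each comparison the 10 called genes with the largest rise and the 10 with the largest fall among those whose libraries did not overlap and whose mean reached 5 TPM in the higher group. It left out unnamed, clone-based, microRNA and small nucleolar RNA symbols. It added up to 2 rises and 2 falls per list with at least 1 TPM, and 14 genes fixed by name. Not all genes and lists that the rule and the design cover are printed. The exact spelling of the pattern for unnamed symbols (open reading frame names and microRNA host genes among them) was set after values had been seen.

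The fit, the fit without day 0 replicate 2 and the list test were tested on simulated data; the other alternatives were not. Libraries were simulated for the real genes with each library's own noise, and 200 of the better expressed genes were changed by known amounts. Recovery of changes in low genes was thus not tested. For day 14 against day 0 over 14203 genes, 28 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were recovered, with 12 false calls among 114. For day 2 against day 0 these were 9 of 50 and 30 of 50, with 6 false calls among 47, and for day 14 against day 2 they were 9 of 50 and 27 of 50, with 1 false call among 37. A simulated shift of the hypoxia list was found by camera with both correlations, and no other list was called with the preset one. The simulated noise was drawn separately for each gene, so this does not test either version on genes that vary together.

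Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter on a mean of at least 5 TPM, median-ratio scaling, quantile normalization, TPM without ribosomal protein genes (no mitochondrially encoded genes were in the table), limma without trend, with robust moderation, with array weights and with a replicate block, fits of only the 2 days compared, and leaving out each library in turn. Leaving out TPM of short RNA symbols and removing a trend on transcript length were added after the data had been seen. The 12 genes drawn per library were picked from the named genes after their values had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.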

Results

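PANC-1, a cell line from a human pancreatic tumour, was profiled by RNA sequencing under combined nutrient and oxygen deprivation, in medium with little glucose, little serum and a reduced amino acid supply. The labels gave 9 samples, 3 each at day 0, day 2 and day 14, and the design stated that cells were collected after 2 and 14 days of deprivation. The question was therefore how the transcriptome of these cells changed early and late in deprivation. The labels gave no undeprived samples at day 2 or day 14. Effects of deprivation thus cannot be told apart from those of time in culture or of a batch by day. The growth protocol was worded identically for all 9 samples, so the labels did not say how the day 0 cells were kept. Each sample had 1 value in TPM (transcript abundance scaled to the library) for each gene symbol, and every sample summed to 1000000 TPM. TPM values keep no record of sequencing depth, so the depth was unknown and no counting interval was given. The labels did not say whether the replicates came from separate cultures, and the p-values below measure only the spread between these samples, which may be technical.

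Pearson correlations across 14144 genes were 0.933 to 0.953 between replicates within day 2 and within day 14, and 0.911 to 0.940 between a day 2 and a day 14 library. These ranges overlap, and day 14 replicate 2 correlated more with day 2 replicate 1 (0.940) than with day 14 replicate 1 (0.934). Day 0 replicates 1 and 3 correlated at 0.972, whereas day 0 replicate 2 correlated with them at 0.870 and 0.875. Genes are not independent replicates, so these values only describe the libraries. Day 0 replicate 2 listed 11363 genes at 1 TPM or more, against 13016 to 13868 in the other 8 libraries. Ribosomal protein genes held 23.8% of its TPM, against 10.2% to 14.9% elsewhere. Its median log2 difference from the mean of replicates 1 and 3 varied with transcript length without a single trend. It was -1.64 for genes of up to 500 nt and 0.42 for those of 500 to 1000 nt, and from there it went down with length to -1.23 over 8000 nt. Day 0 is the reference of the 2 main comparisons, so their counts are also given without this library.

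**Figure D1:**
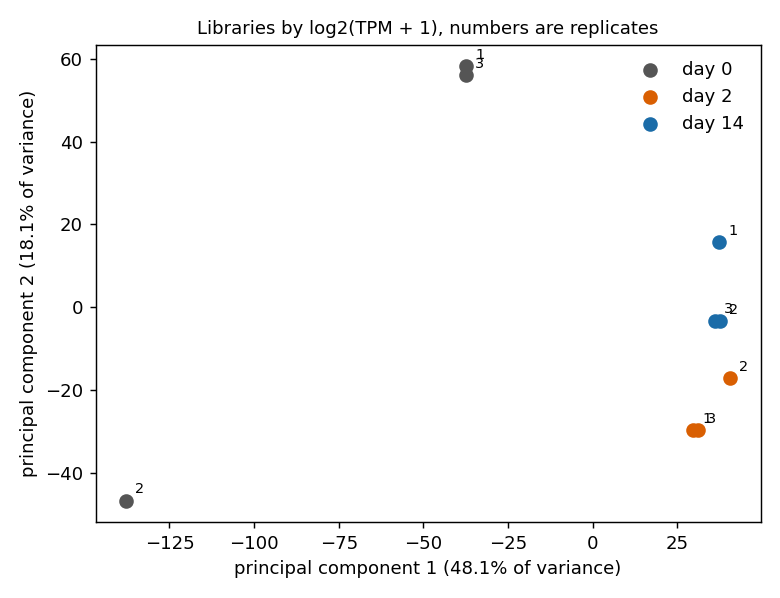
Principal components of log2(TPM + 1) over 14144 genes, 1 point per library, coloured by day and numbered by replicate; the axes give the share of variance. Day 0 replicate 2 lies apart from day 0 replicates 1 and 3, which lie together, and the day 2 and day 14 libraries lie apart from all 3.

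After 2 days of deprivation, 4 of the 10 largest rises were of genes in the hypoxia list and 2 of genes in the amino acid starvation list. NDRG1, a hypoxia-induced gene, went from 3.92 ± 1.39 to 280 ± 55.1 TPM (mean ± SD, n = 3 per day), a log2 change of 5.87 ± 0.52 (SE, adjusted p = 0.00024). DDIT4, an inhibitor of mTORC1 signalling, went from 16.5 ± 5.88 to 962 ± 184 TPM (log2 change 5.83 ± 0.30, adjusted p = 4.58e-05). ATF3, a transcription factor of the integrated stress response, rose by 5.26 on the log2 scale, HMOX1 (haem oxygenase) by 5.07, the fatty acid desaturase SCD by 4.83 and the stress factor NUPR1 by 4.83. PFKFB4 (4.58), VEGFA (4.47), ALDOC (4.38) and the metallothionein MT1F (4.68) completed the 10 largest rises, with adjusted p between 4.58e-05 and 0.0012. The largest falls were NKX6-2, a homeobox gene (log2 change -4.14 ± 0.27, from 44.2 ± 5.91 to 1.63 ± 0.813 TPM), the fatty acid binding protein FABP5 (-3.89) and BCL2A1, a BCL2 family member (-3.81). They were followed by the chemokine CXCL1 (-3.53), the replication factor GINS2 (-3.33), securin PTTG1 (-3.26), the urokinase gene PLAU (-3.16), SNHG25 (-3.12), GTF2H2C (-3.12) and the mitotic kinase MELK (-3.09). PTTG1 was at 178, 776 and 219 TPM in day 0 replicates 1, 2 and 3. The size of its fall, and so its rank, leaned on replicate 2, although its call held without each library in turn. MT1F and GTF2H2C have near-identical copies and their values are uncertain. The call of GTF2H2C was lost without day 2 replicate 3 (adjusted p = 0.056). That of SNHG25 was lost without day 0 replicates 2 and 3 (adjusted p = 0.0701 and 0.0864) or day 14 replicates 1, 2 and 3 (0.0592, 0.0574 and 0.0583).

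The hypoxia response list, fixed before the data were examined, rose as a whole at day 2. All 30 of its measured members were called higher (30 adjusted over the list alone), with a median log2 change of 2.88, or 2.65 above the median of all genes. The set test gave an adjusted p of 4.25e-17, with adjusted p = 0.328 with an estimated correlation. CA9, a membrane carbonic anhydrase used as a hypoxia marker, went from 0.0406 ± 0.0351 to 3.02 ± 0.309 TPM (log2 change 1.95, adjusted p = 0.00441), and the glucose transporter SLC2A1 from 23.2 ± 14.3 to 145 ± 7.12 TPM (2.86, adjusted p = 0.00388). Among the glycolysis genes 12 of 17 rose and none fell (13 and 1 adjusted over the list alone), with ENO2 at 3.37 ± 0.46 beside ALDOC (set test adjusted p = 6.34e-05, and adjusted p = 0.505 with an estimated correlation). There was 1 fall without day 0 replicate 2. GAPDH rose (adjusted p = 0.01), a call lost under quantile normalization (adjusted p = 0.0823). The messages of HIF1A and EPAS1, which encode subunits of hypoxia-inducible factors, did not pass the test. HIF1A was at 27.2 ± 21 and 33.5 ± 3.26 TPM (adjusted p = 0.422) and EPAS1 at 37 ± 26.2 and 46 ± 3.91 TPM (adjusted p = 0.408). Of the 26 nuclear-encoded respiratory chain genes 6 fell (6 adjusted over the list alone) and none rose, with a median relative to all genes of -0.73 and NDUFV2 at -1.39. That count was 13 without day 0 replicate 2, 2 without day 2 replicate 1 and 3 without day 2 replicate 3 (set test adjusted p = 2.34e-05, and adjusted p = 0.392 with an estimated correlation). In the TCA cycle 3 of 17 genes fell (3 adjusted over the list alone), led by SUCLG1 (-1.30) and MDH2 (-1.10), and the set test did not pass (adjusted p = 0.0886). For the TCA genes, leaving out day 0 replicate 2 gave 6 lower and a set test that passed (adjusted p = 0.0271).

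Genes that answer amino acid shortage rose alongside. In the amino acid starvation list 18 of 21 tested members rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 change of 2.23, or 2.00 relative to all genes (set test adjusted p = 1.19e-10, and adjusted p = 0.134 with an estimated correlation). ATF4, the transcription factor that drives this programme, rose from 148 ± 6.63 to 738 ± 35.3 TPM (log2 change 2.31 ± 0.15, adjusted p = 6.74e-05), and asparagine synthetase ASNS from 34.2 ± 8.29 to 166 ± 33.1 TPM (2.26 ± 0.26). The exception was SHMT2, the mitochondrial serine hydroxymethyltransferase, at -1.20 ± 0.17 (2 fell without day 0 replicate 2). Amino acid transporters rose in 9 of 11 cases (10 adjusted over the list alone), led by the cystine transporter SLC7A11 (3.86 ± 0.31) and the glycine transporter SLC6A9 (2.49 ± 0.42), and none fell (set test adjusted p = 0.000107, and adjusted p = 0.392 with an estimated correlation). Among the 18 aminoacyl-tRNA synthetases 13 rose, with AARS at 1.88 and CARS at 1.87, and 3 fell, with KARS at -1.24 and VARS at -1.14 (13 and 4 adjusted over the list alone). The rises numbered 8 without day 2 replicate 1, 2 or 3, and the set test gave an adjusted p of 0.0219, with adjusted p = 0.616 with an estimated correlation. The chaperone list of the endoplasmic reticulum split, with 3 members higher and 7 lower of 18 (4 and 8 adjusted over the list alone). HSPA5 (2.29 ± 0.18) and HERPUD1 (2.15 ± 0.14) rose while SDF2L1 (-2.63 ± 0.37) and MANF (-2.13 ± 0.27) fell, and the set test did not pass (adjusted p = 0.265).

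Lipid synthesis and redox genes also moved up. Of 22 cholesterol synthesis and uptake genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 change of 1.70, or 1.47 relative to all genes (set test adjusted p = 8.79e-07, and adjusted p = 0.156 with an estimated correlation). STARD4, a sterol carrier, rose by 3.71 ± 0.23 and SREBF2, the transcription factor of the pathway, by 3.19 ± 0.45. Of 11 fatty acid synthesis and desaturation genes 6 rose (6 adjusted over the list alone) and none fell, with FADS2 at 3.90 ± 0.43 beside SCD (set test adjusted p = 0.00133, and adjusted p = 0.505 with an estimated correlation). The antioxidant list had 11 of 13 members higher (11 adjusted over the list alone) and none lower, led by HMOX1 (set test adjusted p = 3.04e-05, and adjusted p = 0.392 with an estimated correlation). Autophagy genes rose in 11 of 18 cases and ATG7 fell (12 and 1 adjusted over the list alone), with GABARAPL1 at 3.55 ± 0.32 and the initiating kinase ULK1 called beside it (set test adjusted p = 0.000557, and adjusted p = 0.392 with an estimated correlation). Immediate early genes rose in 7 of 12 cases and 1 fell (7 and 1 adjusted over the list alone), with JUN at 2.78 ± 0.54 and DUSP1 at 2.18 ± 0.30 (set test adjusted p = 0.0183, and adjusted p = 0.505 with an estimated correlation). Lysosomal genes did not move as a set, with 5 of 24 higher and 2 lower (5 and 2 adjusted over the list alone, set test adjusted p = 0.761), or 6 and 4 without day 0 replicate 2. Fatty acid oxidation genes gave 2 higher and 1 lower of 17 (2 and 1 adjusted over the list alone, set test adjusted p = 0.954), or 4 and 2 without day 0 replicate 2, 2 lower without day 0 replicate 1, and 1 higher without day 2 replicate 1, 2 or 3. Single falls were less stable. That of the cholesterol list was lost (0) without any 1 day 2 or day 14 library. That of the immediate early list was lost without day 0 replicate 3, day 2 replicate 1, 2 or 3 or day 14 replicate 2 or 3. There were 2 falls without day 0 replicate 2 in the cholesterol, immediate early and autophagy lists and 1 in the fatty acid synthesis list.

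In the DNA replication list 20 of 22 members were lower (20 adjusted over the list alone) and none higher, with a median log2 change of -1.99 (-2.22 relative to all genes) and FEN1, a flap endonuclease, at -2.75 ± 0.20 beside GINS2 (set test adjusted p = 4.07e-17, and adjusted p = 0.134 with an estimated correlation). In the mitosis list 12 of 20 were lower (13 adjusted over the list alone) and none higher, with cyclin CCNB1 at -2.51 ± 0.29 and AURKB at -2.42 ± 0.34 (set test adjusted p = 7.18e-09, and adjusted p = 0.392 with an estimated correlation). The mitosis count was 20 without day 0 replicate 2 and 7 without day 2 replicate 1. MKI67, the Ki-67 proliferation marker, was at 40 ± 28.7 and 9.32 ± 0.499 TPM with an adjusted p of 0.147, which became 0.00259 without day 0 replicate 2. Nucleotide synthesis genes fell in 8 of 15 cases (8 adjusted over the list alone), with ADSL at -1.44 and PRPS1 at -1.11 (set test adjusted p = 3.04e-05, and adjusted p = 0.392 with an estimated correlation). Ribosome biogenesis genes fell in 7 of 22 cases and rose in 2 (8 and 2 adjusted over the list alone), with NOP16 at -2.78 and BOP1 at -2.43 (set test adjusted p = 0.000247, and adjusted p = 0.392 with an estimated correlation). The falls numbered 14 without day 0 replicate 2, and the rises 1 without day 0 replicate 1 or 3 and 0 without day 2 replicate 1, 2 or 3. MYC, a member of that list, rose by 1.43 (adjusted p = 0.0216), and leaving out day 2 replicate 1, 2 or 3 ended this call (adjusted p = 0.0581, 0.0653 and 0.0651). No cytosolic ribosomal protein gene of 35 was called (0 adjusted over the list alone). Their set test passed narrowly (lower, adjusted p = 0.0483, and adjusted p = 0.786 with an estimated correlation) but turned to higher without day 0 replicate 2 (adjusted p = 0.126), when 8 members were called higher and 1 lower. It was also lost without day 2 replicates 1 and 3 (adjusted p = 0.0785 and 0.0792) or day 14 replicates 1, 2 and 3 (0.062, 0.0558 and 0.053).

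No list of cell identity passed the set test at day 2. By fry, which makes no comparison with other genes, the epithelial and classical subtype lists passed as higher (adjusted p = 0.0163 and 0.00262). The MHC class I and NF-kB lists passed as lower by fry (adjusted p = 0.0295 and 0.0229). Epithelial genes split, with 5 of 17 higher, among them the claudins CLDN3 (2.68) and CLDN4 (2.05), and 4 lower, among them the keratins KRT8 (-2.08) and KRT18 (-1.47), and 9 and 5 adjusted over the list alone (set test adjusted p = 0.628). The rises numbered 3 without day 2 replicate 1, 2 or 3. The classical subtype list had 3 of 6 higher (3 adjusted over the list alone, set test adjusted p = 0.351), among them GATA6 (1.72) and TFF3 (1.51). It had 1 higher without day 2 replicate 2 or 3 and 1 lower without day 0 replicate 1. The basal-like list had 1 higher and 1 lower of 7 (1 and 1 adjusted over the list alone, set test adjusted p = 0.191), and 2 higher without day 0 replicate 2. In the mesenchymal list 1 of 14 rose (1 adjusted over the list alone), and the set test did not pass (adjusted p = 0.415). Its rises numbered 3 without day 0 replicate 1 and 2 without day 0 replicate 3 or day 14 replicate 2. Leaving out day 0 replicate 2 added 5 falls, among them VIM (log2 change -0.55, adjusted p = 0.00443). VIM (adjusted p = 0.521) and CDH1 (0.0656) were not called, and ACTB fell by 1.31 (adjusted p = 0.0052). Among the chromatin modifiers 8 of 24 rose and 1 fell (12 and 1 adjusted over the list alone), with the histone demethylases KDM3A at 3.64 and KDM6B at 3.15 higher and EED at -1.48 (set test adjusted p = 0.149). Without day 0 replicate 2 the counts were 13 and 6. YAP/TAZ targets gave 3 of 12 higher (5 adjusted over the list alone, set test adjusted p = 0.362), with 5 higher and 3 lower without day 0 replicate 2 and 5 higher without day 0 replicate 3. Collagens and matrix genes gave 4 higher and 3 lower of 22 (4 and 3 adjusted over the list alone, set test adjusted p = 0.761), with 6 lower without day 0 replicate 2, 1 lower without day 2 replicate 1 or 3 and 2 higher without day 2 replicate 2 or 3. MHC class I genes gave 3 of 12 lower (3 adjusted over the list alone) and did not pass (adjusted p = 0.0545). They passed without day 0 replicates 1 and 3 (adjusted p = 0.0243 and 0.0282) or day 2 replicate 2 (0.0328), and 1 was lower without day 2 replicate 1 or 3. Interferon genes gave 1 higher and 3 lower of 14 (1 and 3 adjusted over the list alone, set test adjusted p = 0.277), with 5 lower without day 0 replicate 2, 1 without day 0 replicate 1 or day 2 replicate 1 and 0 without day 2 replicate 2 or 3. NF-kB cytokines gave 1 higher and 3 lower of 10 (1 and 3 adjusted over the list alone, set test adjusted p = 0.14), with 0 higher without day 2 replicate 1, 2 or 3 or day 14 replicate 2. Of the markers of other cell types, 3 fibroblast, 2 blood and 0 acinar, islet or hepatocyte markers reached the test, and none was called (1 blood marker lower adjusted over the list alone). The counts without day 0 replicate 2 were 2 lower fibroblast markers and 1 higher and 1 lower blood marker. A fibroblast marker was higher without day 0 replicate 3 (1) and lower without day 14 replicate 3 (1), and a blood marker lower without day 2 replicate 2 (1). The table listed none of the 13 mitochondrially encoded protein genes.

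Over all 14144 tested genes, limma called 4348 at day 2 against day 0, 2715 higher and 1633 lower. Of these, 1751 and 988 changed by at least 2-fold. Without day 0 replicate 2 the 2-fold counts were 1341 higher and 1270 lower. The 62.4% of calls that were higher became 46.7% under median-ratio scaling and 47.9% under quantile normalization, which moved the median log2 change of all genes from 0.23 to -0.05 and -0.02. Without day 0 replicate 2 there were 6800 calls, 3472 higher and 3328 lower, of which 4201 were among the 4348 and none had the opposite sign; without day 2 replicates 1, 2 and 3 there were 2719, 2876 and 2678.

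**Figure D2:**
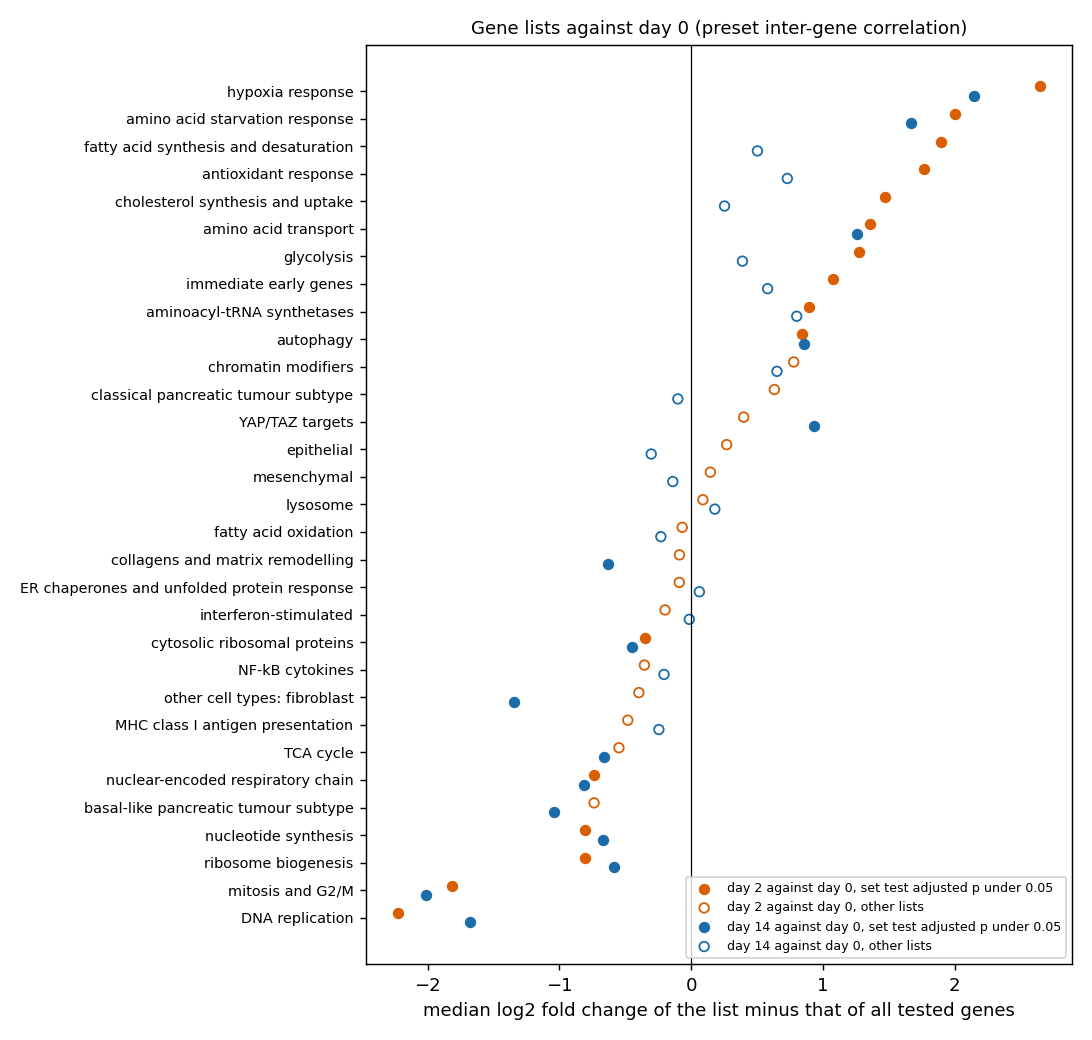
Median log2 fold change of 31 gene lists minus the median of all tested genes (horizontal axis) for day 2 (orange) and day 14 (blue) against day 0; filled points passed the set test with a preset inter-gene correlation. Hypoxia response and amino acid starvation genes lie highest, and DNA replication and mitosis genes lowest, on both days.

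After 14 days ATF3, DDIT4 and NDRG1 were again among the 10 largest rises against day 0. ATF3 reached 125 ± 23.5 TPM (log2 change 5.72 ± 0.38, adjusted p = 0.000107) and TRIB3, a pseudokinase induced by amino acid shortage, went from 19.4 ± 3.71 to 340 ± 23 TPM (4.08 ± 0.18, adjusted p = 3.18e-05). DDIT4 was at 599 ± 137 TPM (5.14 ± 0.30) and NDRG1 at 133 ± 100 TPM (4.51 ± 0.52). NPPC, which encodes C-type natriuretic peptide, went from 1.77 ± 1.08 to 103 ± 11.6 TPM (5.30 ± 0.28, adjusted p = 6.01e-05), TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose by 4.36 and FHL1, a LIM domain protein, by 4.33. The histone genes HIST1H2AC (4.32) and HIST1H4H (4.09), which have near-identical copies and are uncertain, were also among the 10 largest rises. FLICR was listed at 0 in all 3 day 0 libraries and at 32.6 ± 5.29 TPM on day 14 (adjusted p = 0.0104), so no fold is given. The largest falls were NKX6-2 (-4.33), FABP5 (-3.85), PTTG1 (-3.45), ID1, an inhibitor of basic helix-loop-helix factors (-3.40, from 947 ± 384 to 86 ± 19.5 TPM), G0S2 (-3.34), BCL2A1 (-3.19), MT1A (-3.18), CXCL1 (-3.02), GAL (-3.00) and PLK1 (-2.99). MT1A is a multicopy metallothionein and uncertain. The size and rank of the PTTG1 fall again leaned on day 0 replicate 2, where it was at 776 TPM, against 178 and 219 TPM in replicates 1 and 3.

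The hypoxia list stayed high, with 26 of 30 members called higher (28 adjusted over the list alone) and a median log2 change of 2.59, or 2.15 above all genes (set test adjusted p = 7.92e-11, and adjusted p = 0.465 with an estimated correlation). Day 14 replicate 1 was lowest of the 3 day 14 libraries in 24 of the 26. VEGFA, the angiogenic growth factor, was at 129 ± 20.9 TPM (3.98 ± 0.29, adjusted p = 0.000148) and SLC2A1 at 135 ± 21.7 TPM (2.75 ± 0.50). CA9 was at 1.32 ± 1.15 TPM and was not called (adjusted p = 0.0536). HIF1A (adjusted p = 0.399) and EPAS1 (0.279) were not called. Glycolysis genes rose in 8 of 17 cases (10 adjusted over the list alone), with HK2 called beside ENO2 at 2.22, and their set test did not pass (adjusted p = 0.112). Leaving out day 14 replicate 2 or 3 left 4, and the set test passed without day 14 replicate 1 (adjusted p = 0.00551). Respiratory chain genes fell in 5 of 26 cases (5 adjusted over the list alone), with NDUFV2 at -1.20 (set test adjusted p = 2.17e-06, and adjusted p = 0.465 with an estimated correlation). That count was 10 (and 1 higher) without day 0 replicate 2 and 3 without day 14 replicate 2 or 3. TCA cycle genes fell in 2 of 17 cases (2 adjusted over the list alone), SUCLG1 at -1.54 and MDH2 at -0.94 (set test adjusted p = 0.00756, and adjusted p = 0.478 with an estimated correlation), and in 7, with 1 higher, without day 0 replicate 2. The medians of the respiratory chain and TCA lists were -0.37 and -0.22, or -0.81 and -0.66 relative to all genes. Both set tests pointed lower, and neither list passed by fry (adjusted p = 0.071 and 0.188).

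Amino acid starvation genes gave 18 of 21 higher and 1 lower (19 and 1 adjusted over the list alone), with ATF4 at 700 ± 60.8 TPM (2.23 ± 0.15) and ASNS at 196 ± 42.5 TPM (2.49 ± 0.26), and SHMT2 again lower at -1.05 (2 fell without day 0 replicate 2). The set test gave an adjusted p of 1.65e-08, with adjusted p = 0.23 with an estimated correlation. Amino acid transporters rose in 9 of 11 cases (10 adjusted over the list alone), with SLC6A9 at 2.81 and SLC7A11 at 2.78 (set test adjusted p = 0.000543, and adjusted p = 0.478 with an estimated correlation). Autophagy genes rose in 14 of 18 cases and none fell (14 and 1 adjusted over the list alone), with GABARAPL1 at 3.66 ± 0.32 and MAP1LC3B, which encodes a coat protein of autophagosomes, at 2.92 ± 0.21 (set test adjusted p = 0.00126, and adjusted p = 0.478 with an estimated correlation). There was 1 fall without day 0 replicate 2. Aminoacyl-tRNA synthetases gave 12 higher and 1 lower of 18 (13 and 2 adjusted over the list alone), with CARS at 2.12 (set test adjusted p = 0.0604). Their set test passed without day 0 replicate 2 (adjusted p = 0.0475, with 4 lower), day 0 replicate 3 (0.0421) or day 14 replicate 3 (0.0458). The single fall was lost (0) without day 0 replicate 1, day 2 replicate 1, 2 or 3 or day 14 replicate 2 or 3. The endoplasmic reticulum chaperone list was split as at day 2, with 5 higher and 4 lower of 18 (5 and 4 adjusted over the list alone), with HERPUD1 and CRELD2 as the extremes, the latter at -1.42 (set test adjusted p = 0.539). Leaving out any 1 day 2 or day 14 library (replicates 1, 2 and 3 of each) gave 3 higher, and leaving out day 14 replicate 3 gave 2 lower.

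Cholesterol genes gave 12 higher and 1 lower of 22 on day 14 (12 and 1 adjusted over the list alone), with SREBF2 at 2.61 and STARD4 at 2.15 higher and EBP at -1.31. Their set test did not pass (adjusted p = 0.539), with 6 higher without day 14 replicate 2 and 3 lower without day 0 replicate 2. Fatty acid synthesis genes rose in 4 of 11 cases (4 adjusted over the list alone), with SCD at 3.22 and SREBF1 at 1.78 (set test adjusted p = 0.161), and 2 fell without day 0 replicate 2. Antioxidant genes rose in 7 of 13 cases (8 adjusted over the list alone), with TXNRD1 at 2.88 (set test adjusted p = 0.0604), and immediate early genes in 7 of 12 (7 and 1 lower adjusted over the list alone), with EGR1 at 3.04 (set test adjusted p = 0.112). The immediate early count was 4 without day 14 replicate 2 or 3, and 1 gene was lower without day 0 replicate 1. Both sets passed without day 14 replicate 1 (adjusted p = 0.00239 for antioxidant and 0.0105 for immediate early genes). YAP/TAZ targets rose in 9 of 12 cases (10 adjusted over the list alone) with a median log2 change of 1.37 (0.93 relative to all genes), led by CTGF, a matricellular protein, at 3.07 ± 0.30 and AMOTL2 at 2.29 ± 0.55 (set test adjusted p = 0.0306, and adjusted p = 0.66 with an estimated correlation). Leaving out day 14 replicate 2 or 3 left 5, and without day 0 replicate 2 the set test no longer passed (adjusted p = 0.0521) and 1 gene was lower.

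DNA replication genes stayed low, with 17 of 22 lower (20 adjusted over the list alone) and POLE2 at -2.35 ± 0.16 (set test adjusted p = 5.44e-19, and adjusted p = 0.123 with an estimated correlation). Mitosis genes were lower in 13 of 20 cases (15 adjusted over the list alone), with PLK1 at -2.99 ± 0.51 and CCNB1 at -2.80 ± 0.29 (set test adjusted p = 1.55e-14, and adjusted p = 0.465 with an estimated correlation). MKI67 was not called (10.6 ± 5.74 TPM, adjusted p = 0.142) but was called without day 0 replicate 2 (0.00271). Ribosome biogenesis genes gave 6 lower and 3 higher of 22 (6 and 3 adjusted over the list alone), with BOP1 at -1.86 and MYC at 2.18 (set test adjusted p = 0.00884, and adjusted p = 0.478 with an estimated correlation), and 11 lower without day 0 replicate 2. Nucleotide synthesis genes fell in 2 of 15 cases (2 adjusted over the list alone), ADSL at -1.23 and PRPS1 at -0.67 (set test adjusted p = 0.0014, and adjusted p = 0.478 with an estimated correlation), and in 8 without day 0 replicate 2. In that list 1 gene was higher without day 0 replicate 1, 2 or 3. The medians of the ribosome biogenesis and nucleotide synthesis lists were -0.14 and -0.23, or -0.58 and -0.67 relative to all genes. Both set tests pointed lower, and neither list passed by fry (adjusted p = 0.403 and 0.0984). No ribosomal protein gene of 35 was called (0 adjusted over the list alone), although the set test passed narrowly (lower, adjusted p = 0.0435, and adjusted p = 0.743 with an estimated correlation). Without day 0 replicate 2 it pointed higher (adjusted p = 0.0521), with 15 members called higher and 1 lower, and it was lost without day 14 replicate 2 (0.0849). Under quantile normalization it also pointed higher (adjusted p = 0.403).

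Epithelial genes were again split, 5 higher and 5 lower of 17 (7 and 6 adjusted over the list alone), with CLDN1 at 2.42 and TJP1 at 2.07 against KRT8 at -1.89 and KRT19 at -1.83 (set test adjusted p = 0.154). Mesenchymal genes gave 5 higher and 1 lower of 14 (5 and 1 adjusted over the list alone), with CDH2 at 1.34 higher and VIM at -1.07 lower (set test adjusted p = 0.957). Without day 14 replicate 2, 2 were higher, and without day 14 replicate 1 or 3, 3 were. There were 2 lower without day 0 replicate 2. The VIM call was lost without day 14 replicate 3 (adjusted p = 0.0544). The classical subtype list split, with the transcription factor GATA6 at 2.23 and the secreted protein AGR2 at -2.99 (2 higher and 2 lower of 6, also adjusted over the list alone, set test adjusted p = 0.421). Its rises numbered 1 without any 1 library but day 14 replicate 1, and its falls 1 without day 0 replicate 2 or 3 or day 2 replicate 1. The basal-like list gave 1 higher and 2 lower of 7 (1 and 3 adjusted over the list alone, set test adjusted p = 0.0304, and adjusted p = 0.465 with an estimated correlation), a call lost without day 0 replicate 2 (0.328, with 2 higher) or day 14 replicate 3 (0.0673). Its falls numbered 1 without day 0 replicate 1, day 2 replicate 2 or day 14 replicate 1 or 3. Its set test pointed lower, with a median of -0.60, or -1.04 relative to all genes, and it did not pass by fry (adjusted p = 0.0984). Collagens and matrix genes gave 3 higher and 3 lower of 22 (3 and 3 adjusted over the list alone), with THBS1 at 2.52 and COL13A1 at -1.71 (set test adjusted p = 0.0304, and adjusted p = 0.671 with an estimated correlation), and 9 lower without day 0 replicate 2. Their set test was lost without day 0 replicates 1 and 3 (adjusted p = 0.229 and 0.124) or day 14 replicate 1 (0.0896). It pointed lower, with a list median of -0.19, or -0.63 relative to all genes, and the list did not pass by fry (adjusted p = 0.927). Of the 3 fibroblast markers that reached the test 2 fell (3 adjusted over the list alone), COL3A1 at -0.90 and THY1 at -0.77 (set test adjusted p = 0.00756, and adjusted p = 0.465 with an estimated correlation), and without day 0 replicate 1 COL3A1 did not reach the test and the call of THY1 was lost (0.105). The falls numbered 0 without day 0 replicate 1 or 3, day 2 replicate 3 or day 14 replicate 1 or 2, and 1 without day 2 replicate 1 or 2 or day 14 replicate 3. With 1 library left out the adjusted p reached 0.0618 for COL3A1 (day 14 replicate 2) and 0.139 for THY1 (day 14 replicate 1). Lysosome (7 higher and 2 lower of 24), fatty acid oxidation (2 and 2 of 17), chromatin modifier (12 and 1 of 24), interferon (2 and 0 of 14), NF-kB cytokine (3 and 3 of 10) and MHC class I (1 and 1 of 12) lists did not pass the set test, with adjusted p of 0.112 to 0.867. Adjusted over the list alone, these lists gave 8 and 2, 2 and 2, 12 and 1, 2 and 0, 4 and 4, and 0 and 0. The lysosome list had 3 higher without day 14 replicate 1 or 2 and 4 without day 2 replicate 1 or 3. It had 1 lower without any 1 library but day 0 replicates 2 and 3. Chromatin genes had 6 higher without day 14 replicate 2 or 3. NF-kB genes had 1 higher without day 2 replicate 2 or 3 or day 14 replicate 1, 2 or 3. Fatty acid oxidation genes had 1 higher without day 14 replicate 1 or 2. Leaving out day 0 replicate 2 gave 5 lower chromatin genes, 2 lower interferon genes and 4 higher and 2 lower MHC genes. The interferon list had 1 lower without day 0 replicate 3. The MHC list had 2 higher without day 0 replicate 1 or 3 and 0 without day 14 replicate 2. It had 2 lower without day 0 replicate 1 and 0 without day 0 replicate 3 or any 1 day 2 or day 14 library. GAPDH was not called (adjusted p = 0.242). Nor were ACTB (0.0694) and CDH1 (0.27), which were called without day 0 replicate 2 (0.00446 and 0.0254).

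At day 14 against day 0 limma called 4841 of 14144 genes, 3890 higher and 951 lower. Of these, 2465 and 554 changed by at least 2-fold. Without day 0 replicate 2 the 2-fold counts were 1774 higher and 711 lower. The 80.4% of calls that were higher became 45.8% under median-ratio scaling and 49.6% under quantile normalization, which moved the median log2 change of all genes from 0.44 to -0.05 and -0.01. Without day 0 replicate 2 there were 6913 calls, 4875 higher and 2038 lower, of which 4676 were among the 4841; without day 14 replicate 2 there were 3141.

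**Figure D3:**
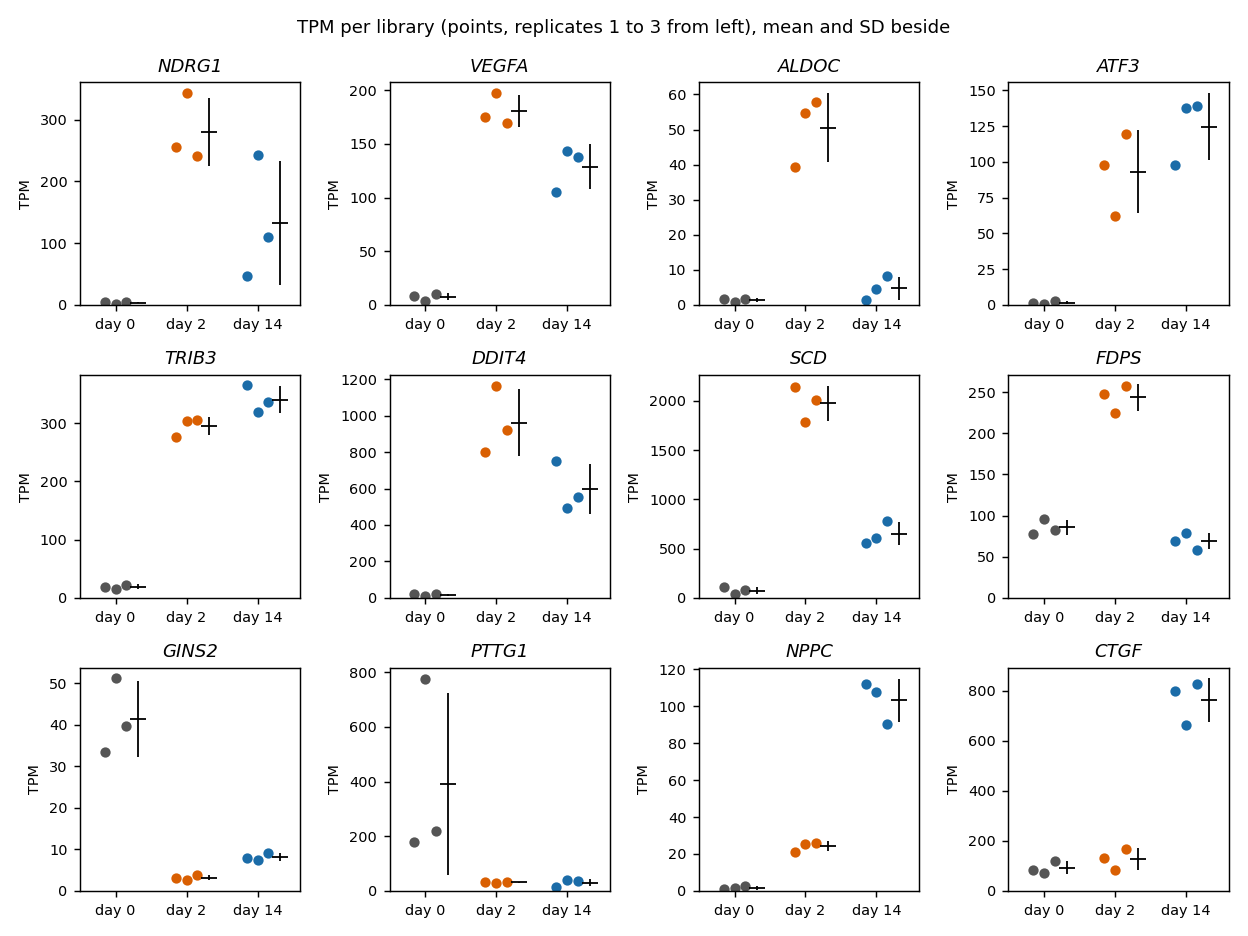
TPM of 12 named genes in each library (points, replicates 1 to 3 from left within a day), with the mean and SD beside them (bars, n = 3). NDRG1, VEGFA, ATF3, TRIB3, DDIT4 and SCD are higher on both later days in all libraries, GINS2 and PTTG1 are lower, FDPS and ALDOC are higher on day 2 than on day 14, and NPPC and CTGF are higher on day 14 than on day 2.

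Day 14 was then compared with day 2, to ask what changed as deprivation went on. Several sterol synthesis genes were lower on day 14. FDPS, which makes farnesyl diphosphate, went from 244 ± 16.8 to 69.1 ± 10 TPM (log2 change -1.81 ± 0.17, adjusted p = 0.0126), MVD from 98.3 ± 9 to 27.2 ± 2.47 TPM (-1.82 ± 0.24, adjusted p = 0.031) and ACAT2 from 77.2 ± 14.6 to 20.8 ± 3.07 TPM (-1.83 ± 0.24). In the cholesterol list 6 of 22 members fell (15 adjusted over the list alone) and none rose, with a median log2 change of -0.98, or -1.21 relative to all genes. Its set test passed with the preset correlation (adjusted p = 1.18e-29) and with an estimated correlation (adjusted p = 0.00939), the only list test of the 3 comparisons to do so. Leaving out day 0 replicate 2 gave 17 falls, day 0 replicate 1 or 3 gave 2, day 14 replicate 2 or 3 gave 1, and day 2 replicate 1, 2 or 3 or day 14 replicate 1 gave 0.

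The protease HTRA3 (-3.53 ± 0.38, from 25.8 ± 6 to 1.52 ± 1.21 TPM), the aldolase ALDOC (-3.33 ± 0.44) and the ferroxidase CP (-2.28 ± 0.28) had the largest falls, followed by OSGIN1 (-2.11), ELF3 (-2.03), COL7A1 (-1.93) and UPK1A (-1.67). The largest rises were CTGF (2.63 ± 0.30, from 127 ± 43.7 to 762 ± 87.9 TPM, adjusted p = 0.0189), CBLN2 (2.23), FHL1 (2.19), NPPC (2.05), MOK (2.04), the WNT antagonist DKK1 (2.01, from 193 ± 39.4 to 776 ± 103 TPM), IL32 (1.96), HIST1H2AD (1.84), FAM84B (1.81) and the integrin ITGB8 (1.66). HIST1H2AD has near-identical copies and is uncertain. All 20 were also called without day 0 replicate 2, with adjusted p of 0.000317 to 0.00847. Of the 22 named genes called between these days, 0 kept the call without each library in turn. The 14 genes fixed by name were not called, with ATF4 at -0.08 and ASNS at 0.23, a sign that turned under scaling. Leaving out day 0 replicate 2 called 6 of them: CDH1 (-1.53, adjusted p = 0.00904), VIM (-0.84, 0.00589), MYC (0.74, 0.0182), ACTB (0.66, 0.0213), GAPDH (-0.98, 0.0238) and VEGFA (-0.50, 0.0471).

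Other lists had few called members. Antioxidant genes had 2 of 13 lower (8 adjusted over the list alone), OSGIN1 and GCLC, the catalytic subunit of glutathione synthesis, at -1.51 (set test adjusted p = 8.22e-15, and adjusted p = 0.112 with an estimated correlation). Glycolysis had 1 of 17 lower (7 adjusted over the list alone), ALDOC, with a list median of -0.74, or -0.98 relative to all genes (set test adjusted p = 1.45e-12, and adjusted p = 0.263 with an estimated correlation). No member of the hypoxia list was called (1 lower adjusted over the list alone), with a median of -0.52, or -0.76 relative to all genes (set test adjusted p = 6.54e-14, and adjusted p = 0.263 with an estimated correlation). Day 14 replicate 1 was lower than the other day 14 libraries in the hypoxia genes called on day 14 (median log2 difference -0.84). Part of the fall of this list thus lies in that library. No fatty acid synthesis gene was called (5 lower adjusted over the list alone; median -0.89, or -1.13 relative to all genes, set test adjusted p = 1.38e-09, and adjusted p = 0.263 with an estimated correlation). DNA replication genes had a median of 0.51, or 0.27 relative to all genes, and no call (6 higher adjusted over the list alone, set test adjusted p = 0.000176, and adjusted p = 0.304 with an estimated correlation). In the classical subtype list TFF3 fell by 1.20 (3 lower adjusted over the list alone, set test adjusted p = 6.59e-05, and adjusted p = 0.0877 with an estimated correlation). CTGF was the 1 called YAP/TAZ target (4 adjusted over the list alone), with a set test adjusted p of 0.0556, under 0.05 without any of 5 libraries (day 0 replicates 2 and 3, day 2 replicates 1 and 3 and day 14 replicate 1, at 0.0368, 0.0397, 0.0214, 0.0249 and 0.0218). The mitosis test (lower, adjusted p = 0.00158, and adjusted p = 0.602 with an estimated correlation) was lost without day 14 replicate 1 (0.876). Of the called members, those of the antioxidant and classical lists fell to 0 without any 1 library but day 0 replicate 2, that of glycolysis without any 1 but day 0 replicate 2 and day 14 replicate 3, and that of YAP/TAZ without any 1 day 2 or day 14 library. Leaving out day 0 replicate 2 raised the called members to 9 for hypoxia, 10 for glycolysis, 8 for antioxidant, 8 for fatty acid synthesis, 14 for DNA replication, 6 for YAP/TAZ genes and 3 (1 higher and 2 lower) for the classical subtype. In all, 17 of 32 lists passed with the preset correlation, 4 higher and 13 lower.

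Of 14144 genes, limma called 59 between day 14 and day 2, 30 higher and 29 lower, while 2558 had an unadjusted p under 0.05. The shares higher were 50.8% as deposited, 28.6% under median-ratio scaling and 35.2% under quantile normalization. The count rested on the spread shared with day 0: it was 3854 without day 0 replicate 2 (including all 59), 2519 when only the 6 libraries of these days were fitted, 14 and 24 without day 0 replicates 1 and 3, and 0, 2, 0, 4, 4 and 10 when a library of day 2 (replicates 1 to 3) or day 14 (replicates 1 to 3) was left out.

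The changes of day 2 and day 14 against day 0 resembled each other across genes. Among the genes called on each day, 2302 were higher on both and 815 lower on both, against 747 and 110 for independent lists of these sizes, and 1 gene was called in opposite directions. The correlation of the log2 changes across genes was 0.843. Both comparisons share the day 0 libraries, and simulated groups with no effect gave a mean of 0.715 and a maximum of 0.745 over 100 simulations. The simulated noise was drawn separately for each gene. Noise that genes share within a library is thus left out, and the simulated range may be too narrow. In 20 simulations with no effect almost no gene was called and the overlap averaged 0 higher and 0.05 lower genes, which gives no reference for the overlap of calls. The covariance was 0.715, against 0.193 in the simulations, a difference of 0.522. The 3 day 0 libraries cannot be split into 2 sets of at least 2, so part of the excess may come from the shared controls. Without day 0 replicate 2 the correlation was 0.83, against 0.368 in the simulations. An F test over the 3 days called 5009 of 14144 genes, and 8744 without day 0 replicate 2.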

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

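The tests on replicate 2 of day 0 (except for the length trend as the whole of its distance), the sequence match of the 2 short entries and the test for day 0 material in day 14 replicate 1 were chosen after the result was seen.

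The difference between the day 14 and the day 2 change from day 0 is the day 14 against day 2 comparison itself, so the values below restate that comparison and are no separate test. They cover the 20 genes the naming rule took from it and 1 list. Higher on day 14 were CTGF (log2 difference 2.63), CBLN2 (2.23), FHL1 (2.19), NPPC (2.05), MOK (2.04), DKK1 (2.01), IL32 (1.96), HIST1H2AD (1.84), FAM84B (1.81) and ITGB8 (1.66). Lower were HTRA3 (-3.53), ALDOC (-3.33), CP (-2.28), OSGIN1 (-2.11), ELF3 (-2.03), COL7A1 (-1.93), ACAT2 (-1.83), MVD (-1.82), FDPS (-1.81) and UPK1A (-1.67), and the median of the cholesterol synthesis and uptake list was -0.98. For CTGF, CBLN2, DKK1 and ITGB8 the change was called against day 0 on day 14 and not on day 2. For HTRA3, ALDOC, CP, COL7A1, ACAT2, MVD and FDPS (higher, HTRA3 by 4.31 on the log2 scale) and MOK and IL32 (lower) it was called on day 2 and not on day 14. MOK, DKK1, CP, COL7A1, ACAT2 and FDPS had opposite signs on the 2 days, and none was called in both directions.

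Only 10 splits of the 6 libraries of 2 days exist, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many called genes: 3105 for day 2 against day 0 with 13 as the highest of the others, 2927 and 13 for day 14 against day 0, and 2519 and 12 for day 14 against day 2. For the F test over the 3 days 100 of the 280 possible splits were drawn. Of these, 1, the real one, gave as many genes (5009, highest other 2879), which argues against a random assignment of libraries to days. Chance differences between cultures cannot be excluded this way, since the labels did not say whether the replicates came from separate cultures.

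Day 0 replicate 2 lay far from the other day 0 libraries. Its root mean square log2 distance from the mean of replicates 1 and 3 was 1.24, against 0.474 between those replicates. With a trend on transcript length removed the distance was still 0.924 (0.47 between replicates 1 and 3), which argues against a length trend as the whole cause. Its difference from them correlated with transcript length at -0.423 (0.12 for replicate 1 minus 3), so a dependence on length could be part of it. A plain loss of long transcripts would not describe it, since genes of up to 500 nt were lowest (median -1.64 for 595 genes, against 0.42 at 500 to 1000 nt and -1.23 over 8000 nt). Of 475 genes changed at least 4-fold between day 0 and day 2 without this library, 86.7% lay nearer to day 0 in it (85.7% of 342 such genes for day 14), which argues against a day 2 or day 14 sample under its label. The highest of 11 abundant markers of other cell types was COL1A1 at 9.88 TPM, just under the bound of 10 set for this test and below the 60.8 TPM of another day 0 library. HBA1, at 4.21 TPM against 0.949, and APOA1, at 0.414 TPM against 0.0571, went the other way. In this library HBB, PRSS1, CPA1, INS and ALB were at 0 TPM, COL1A2 was at 0.00782 TPM, and CD74 was at 0.191 TPM against 0.762. Cells of the fibroblast, blood, acinar, islet or hepatocyte types would bring all their abundant transcripts, so these values argue against RNA of those types as the cause of the distance. The rest of the distance stayed open, and no biological explanation was tested, since the design names none within a day.

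The entries MIR6723 and MIR4461 together held 22.4% to 40.3% of the TPM of each library. MIR6723 matched the opposite strand of the mitochondrial MT-CO1 over 98.9% of its bases and MIR4461 that of MT-ND4L over 94.6%, with at most 48.7% for any other mitochondrial transcript. Reads of mitochondrial transcripts assigned to these entries are a candidate explanation, since the table lists no mitochondrially encoded gene. Weighted by length the entries held 1.01% to 2.03%, which argues against a large share of the reads. No biological explanation was tested.

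The hypoxia genes called on day 14 were lower in day 14 replicate 1 than in the other day 14 libraries, with a median log2 difference of -0.84 (median absolute deviation 0.66), and 24 of 26 were lowest there. NDRG1 was at 46.9, 243 and 109 TPM in replicates 1, 2 and 3. The amino acid starvation genes that rose differed by a median of only -0.15 (deviation 0.36). On the deposited scale this argues against a share of day 0 cells or RNA. The median difference of all genes was 0.11, so relative to all genes the amino acid difference was larger. On that scale the bounds set for the test do not decide the question. The hypoxia difference was -0.94 with the length trend removed and -0.95 relative to all genes, which argues against length or scaling. A difference in oxygen between cultures stays open and untested, since the labels give no oxygen level.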

How the results depend on the processing

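The alternatives without short RNA symbols and with the length trend removed were chosen after the data had been seen, and the cause of the changes below was not tested unless given.

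For day 2 against day 0 (4348 genes), only array weights (8975) and left-out libraries (2678 to 6800) moved the count by over 1.5 times. For day 14 against day 0 (4841) these gave 8455 and 3141 to 6913, the filter at a mean of 5 TPM, which tests fewer genes, gave 3214, and only the 2 days compared, with fewer libraries, gave 2927. The F test count (5009) became 10642 with array weights and 3465 to 8744 with a library left out. Array weights gave day 0 replicate 2 a weight of 0.038. With a replicate block the counts were 3290, 3771 and 3541 (F test). No pairing by replicate number was found, with 0 of 9 pairs correlating over 0.1. That check used deviations from means of 3 libraries, day 0 replicate 2 among them, so it cannot exclude a pairing.

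The day 14 against day 2 count (59) was the least stable: 6 and 127 with pseudocounts of 0.1 and 5, 24 at a mean of 5 TPM, 133 with median-ratio scaling, 341 with quantile normalization, 131 without ribosomal protein genes, 5052 with array weights, 2 with the replicate block, 2519 with only the 2 days compared, 27 without short RNA symbols, 337 with the length trend removed and 0 to 3854 with a library left out. Where limma called 0, without day 2 replicate 1 or 3, 1471 and 1624 genes had an unadjusted p under 0.05.

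With an estimated correlation 0, 0 and 1 lists passed for the 3 comparisons, against 16, 15 and 17 with the preset one, and fry gave 8 for day 14 against day 2. For day 2 against day 0 fry gave 13 higher and 7 lower, with 15 shared, against 10 higher and 6 lower with the preset correlation. The 15 lists of day 14 against day 0 were 5 higher and 10 lower. There fry gave 12 higher and 3 lower, with 8 shared, and the 3 lower were DNA replication, mitosis and fibroblast markers. Its higher lists included cholesterol (adjusted p = 0.00242), fatty acid synthesis (0.0214), antioxidant (0.00971) and immediate early genes (0.011), which did not pass with the preset correlation. Quantile normalization gave 9 higher and 6 lower, and the filter at a mean of 5 TPM gave 7 and 6, each with 11 shared. With a library left out 15 to 17, 13 to 17 and 15 to 19 passed.

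Lists whose test passed before or after the turn changed direction as follows, with adjusted p. Lists that passed in neither also turned, such as the mesenchymal list against day 0 without day 0 replicate 2. Cytosolic ribosomal proteins turned higher for day 2 against day 0 without day 0 replicate 2 (0.126; left-out libraries 0.000427 to 0.126, all alternatives up to 0.786). For day 14 against day 0 they did so with quantile normalization (0.403), fry (0.908) and without day 0 replicate 2 (0.0521; left-out libraries 0.000352 to 0.0849). For day 14 against day 2 they did so with quantile normalization (0.0097; all alternatives up to 0.995). Endoplasmic reticulum chaperones turned higher for day 14 against day 0 with fry (0.00337; up to 0.743), and mitosis for day 14 against day 2 without day 14 replicate 1 (0.876; left-out libraries 1.29e-07 to 0.876).

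No named gene changed direction while called. Of the named genes called, 78 (day 2 against day 0), 83 (day 14 against day 0) and 0 (day 14 against day 2) kept the call in all settings run. The correlation of the day 2 and day 14 changes was 0.81 to 0.87 with a library left out. Depth is unknown, so what it limits could not be computed.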

Other observations

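All tests of this part were chosen after the values had been seen.

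Some heat shock protein genes of the cytosol and mitochondria fell on day 2. HSPE1 (log2 change -2.12), HSPH1 (-1.98), HSPB1 (-1.92), HSPA8 (-1.90), HSP90AA1 (-1.55) and HSP90AB1 (-1.48) were called lower at day 2. Of 18 such genes 9 fell and 2 rose, with a class median of -0.79 (-1.02 relative to all genes), and on day 14 8 fell and 1 rose (-0.61, or -1.05 relative). Leaving out day 0 replicate 2 gave 12 falls and 2 rises on day 2, and 11 falls and 2 rises on day 14. The day 2 class median lay at percentile 0.02 of 10000 random lists of like level. The class was looked at because its members fell, and random lists leave out the correlation between genes, so this does not test whether they fall as a class.

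Of 42 histone symbols 26 rose and 1 fell on day 14, with a median of 1.80 (1.36 relative to all genes), and 20 rose and none fell on day 2 (1.16, or 0.93 relative). The day 14 class median lay at percentile 100 of 10000 random lists, and day 2 was not tested this way. This has the same limits and does not test whether they rise as a class. The histone genes have near-identical copies, and whether reads were moved between copies, or RNA without a poly(A) tail was kept, was not tested.

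Transcripts that host small nucleolar RNAs were looked at for the same reason and gave a negative result on day 2. Of 22, 5 rose and 3 fell on day 2 (8 and 4 without day 0 replicate 2), and the class median lay at percentile 65.7 of random lists. On day 14 against day 0, 6 rose and 1 fell (10 and 1 without day 0 replicate 2), with a median of 0.64, or 0.20 relative to all genes. Between day 14 and day 2, 0 were called, or 11 higher without day 0 replicate 2. These 2 comparisons were not set against random lists.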
